A study of Arabidopsis thaliana with 6 samples.

How the data were processed

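The series holds 6 leaf small RNA libraries, 3 of WT and 3 of rdr1, from plants grown with 16 h of daylight at 22 °C, with RNA extracted by TRIzol, libraries made with HD adapters and 50-nt single-end reads from an Illumina HiSeq instrument, per the labels' protocols. The genome build was TAIR10, per the submitters' processing notes. Read trimming, the aligner, the filters and the normalisation are not given in the sources used here. The deposited values are a normalised signal per distinct sequence and library, never negative, with 1 column per library per the file headers. Every value is a whole multiple of a step that is fixed within a library, within 0.01 of a read for 100% of values, and each step is 8000000 divided by a whole number, which was taken as the library total used for scaling; what that total counts is not stated. The table held 18124 sequences with 0 duplicates, and each reached at least 20.07 in a library, so a sequence below this in all 6 libraries was not analysed here.

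Sequences were matched without mismatch to the reference genome (TAIR10.1) and its annotation; all 18124 matched, 2159 at 1 place. Because the files held a normalised signal, not raw counts, each sequence with a mean of at least 5 over the 6 libraries was tested with limma (empirical Bayes with trend, two-sided) on log2 of the value plus 1. Fold changes are on that scale, which understates changes of low values. The false discovery rate was controlled by Benjamini-Hochberg adjustment with a threshold of 0.05. The same fit was made for sums per miRNA family (60 families) and per annotated gene (1217 loci tested), in which a sequence with several matches was divided equally between them. Shares of the summed value by length and by annotation class were compared with exact two-sided permutation tests, which with 3 against 3 cannot give a p below 0.1. Each sequence took the first class that applied, in the order miRNA, trans-acting siRNA, tRNA, rRNA, small nuclear and nucleolar RNA, chloroplast, mitochondrion, protein-coding gene and other nuclear; transposable elements were not analysed here.

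Mature miRNAs were matched by exact sequence, 36 of 69 in a list fixed before the data were examined and 76 of 350 in the annotation. Lists fixed in the same way were the miR159 family, the miR159 and miR319 superfamily, copper-responsive, phosphate-starvation, sulfate and nitrogen responsive, age pathway, auxin pathway, leaf polarity, small RNA pathway regulating, secondary siRNA trigger and Brassicaceae-specific miRNAs, trans-acting siRNAs, and pollen-enriched miRNAs as markers of another organ. Of the auxin pathway list 5 of 7 members were measured, of the Brassicaceae-specific list 10 of 18, of the secondary siRNA trigger list 3 of 9 and of the sulfate and nitrogen list 2 of 6, and 0 of these passed the test. Lists with at least 2 measured members were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. The text names the RDR1 locus, miR159, the members of lists of at most 5, miRNAs past the threshold or else the 10 with the smallest p, the 5 other sequences with the largest rise and fall among called sequences whose groups do not overlap, and called loci; MIR774a was named after its value was seen. A lower bound on a fold uses a floor of 3 reads over the libraries of a group.

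Alternatives set before the data were examined were other pseudocounts (0.5, 5 and 20), no filter on low values, a mean of at least 20, median of ratios scaling, a common total, quantile normalisation, array weights, the replicate number as a block, each library left out in turn, sums over 3′ variants of up to 2 nt, and edgeR and DESeq2 on recovered reads. Scaling to the miRNA sum, edgeR with TMM factors, removal of WT replicate 1 and rdr1 replicate 1 together, sums by strand and the rRNA split by strand were chosen after the data were seen. No pair of libraries of a genotype agreed within sampling noise (chi-square over its degrees of freedom from 10.7 to 61.7), so none was treated as a repeat deposit of another library; this does not show that they came from separate plants. On simulated reads for the sequence comparison (18043 sequences), limma recovered 8% of 4-fold and 69% of 16-fold changes, with 3 false calls among 80. For loci (1217) it recovered 61% and 99%, with 11 false calls among 171, and for families (60) 75% and 100%, with 1 false call. The simulated sequences, loci and families were each drawn independently, without differences shared across a library such as those in fragment length. These recovery and false-call numbers therefore need not hold for the real libraries. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.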

Results

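Small RNAs were sequenced from leaves of wild-type (WT) Arabidopsis thaliana and of the rdr1 mutant, with 3 libraries of each genotype. RDR1 is an RNA-dependent RNA polymerase, an enzyme that copies single-stranded RNA into double-stranded RNA, from which Dicer-like proteins cut small interfering RNAs. The design asks which small RNAs differ in abundance in rdr1, and the series title names a lower level of miRNA159b. The table held 18124 distinct sequences of 17 to 34 nt, each with a normalised read count scaled to 8000000 reads of a library total. The library totals behind this scaling were 5499464, 8988961 and 9955668 reads in WT replicates 1 to 3 and 6377499, 4668411 and 6601783 reads in rdr1 replicates 1 to 3. The listed sequences held between 23.8% and 30.9% of these totals. A single read was worth between 0.804 and 1.71 on the scale of the values, and all values given here without another unit are on that scale.

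The libraries differed in fragment length in a way that genotype did not explain. Sequences of 28 to 34 nt made up 35.3%, 26.2% and 9.94% of the summed value in WT replicates 1 to 3, against 4.87%, 15.7% and 17.7% in rdr1 replicates 1 to 3. Sequences of 17 to 19 nt made up 35.2% in rdr1 replicate 1 and 5.72% in WT replicate 1, and between 13.6% and 18.2% in the other 4 libraries. The log2 values of WT replicate 1 and rdr1 replicate 1 correlated across sequences with a Pearson r of 0.187, and sequences are not independent replicates. The labels do not say that the 3 libraries of a genotype came from separate plants, so the p-values rest on the spread between these samples, which may be technical. In limma, empirical Bayes with trend draws the spread of each sequence towards that of sequences of similar mean. For single sequences the limma SEs and p-values therefore reflect mostly this shared spread, and not a sequence's own spread between the libraries. The RDR1 gene itself (AT1G14790, chromosome 1, 5093961 to 5098270, minus strand, TAIR10.1) matched 0 of the sequences listed, so the genotype labels could not be checked from these data, and small RNAs do not measure its mRNA.

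**Figure D1:**
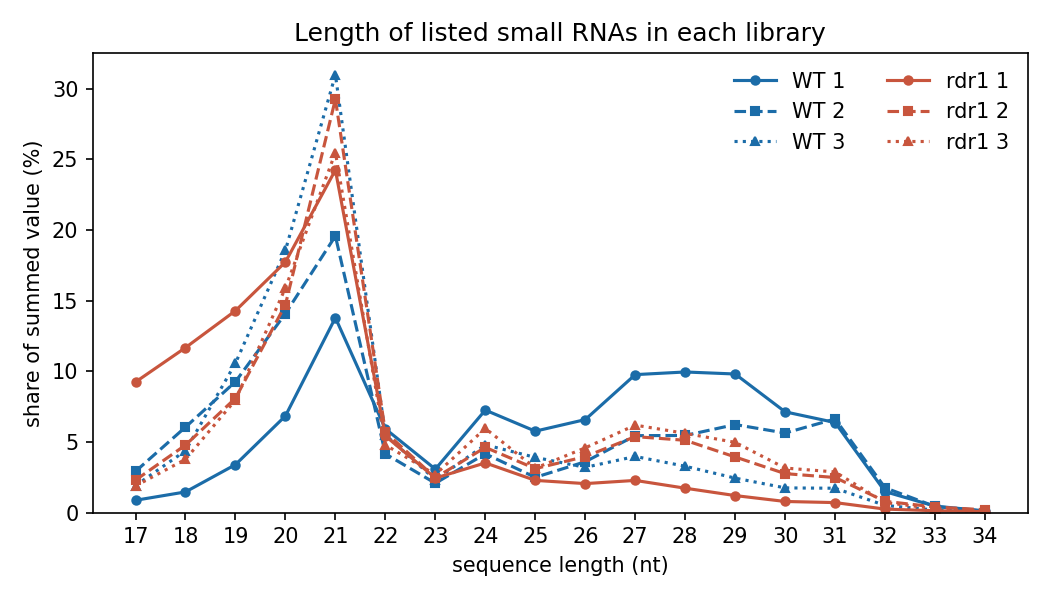
Share of the summed normalised value (vertical axis, %) by sequence length (horizontal axis, nt) in each of the 6 libraries, 3 WT in blue and 3 rdr1 in red. The 21-nt share was 21.4% ± 8.74 in WT and 26.3% ± 2.61 in rdr1 (SD, n = 3 each), and WT replicate 1 and rdr1 replicate 1 lay at opposite ends for long and short fragments.

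Sequences antisense to nuclear ribosomal RNA made up 21 of the 36 small RNA sequences that fell in rdr1. Their part varied between tests, at 26 of 59 falls with edgeR, 41 of 123 with DESeq2, and 44 of 786 with limma and array weights. With limma and a library left out in turn it ranged from 26 of 62 without rdr1 replicate 1 to 9 of 11 without WT replicate 3. Of 18043 sequences tested, 39 passed the limma test at a Benjamini-Hochberg adjusted p under 0.05, with 36 lower and 3 higher in rdr1. Of the 36, 22 matched rRNA, 11 matched other nuclear sequence, 2 matched protein-coding genes (AT2G02440 and AT1G70080, described with the loci) and 1 was miR159b-5p. At an unadjusted p under 0.05 there were 442 sequences, of which 123 were higher in rdr1. The 442 were a smaller part of the 18043 than the 0.05 expected of unchanged sequences. On the reads recovered from the values, edgeR called 67 sequences (36 of them among the 39) and DESeq2 called 142 (37 of them among the 39). The number called was 11 without WT replicate 2, 11 without WT replicate 3, 22 without WT replicate 1 or rdr1 replicate 2, and 72 without rdr1 replicate 1. With the deposited scaling the median log2 fold change of all tested sequences was 0.47, against 0.03 with median of ratios scaling, so that a sequence at 0.47 lay at the middle of the distribution.

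Antisense rRNA sequences were found at 13 sites of the nuclear rRNA unit (chromosome 2, 3706 to 10237, TAIR10.1, with a second annotated copy at chromosome 3, 14197677 to 14204208), and their choice as a group came after their values were seen. The 45 antisense sequences of 17 to 26 nt summed to 4783 ± 2224 in WT and 156 ± 57.5 in rdr1 (SD, n = 3 each), a ratio of 30.6. This ratio of sums is not that of each site. The site from 5936 to 5968 held 3784 of the WT sum. The site from 4299 to 4320, whose groups overlapped, held 96.8 of the rdr1 sum. All 45 were lower in rdr1. Groups did not overlap for 42 of them, against 5.29% of all tested sequences (10% by chance in either direction). Of the 45, 23 had 0 reads in all 3 rdr1 libraries, and 21 passed the limma test. Sequences within a site overlap, so the 45 are not independent of each other. By an exact two-sided permutation test of the sums, p was 0.1, the smallest that 3 against 3 can give. The number of these sequences called was 13, 7 and 9 without WT replicates 1, 2 and 3 in turn.

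The largest antisense site spanned the 3′ end of the 5.8S rRNA gene, which ends at 5945 (positions 5936 to 5968 of chromosome 2). Its 22 sequences, 15 of them called, summed to 3784 ± 1985 in WT and 17.7 ± 4.05 in rdr1. A site at the 3′ end of the 18S rRNA gene, which ends at 5513 (positions 5512 to 5536), held 8 sequences, 5 of them called, with 494 ± 174 in WT and 3.79 ± 2.23 in rdr1. Near the 5′ end of the 18S rRNA gene (positions 3810 to 3831), 3 sequences, 1 of them called, summed to 116 ± 8.57 in WT and 0.571 ± 0.989 in rdr1. The sites at 4299 to 4320 (124 ± 28.1 in WT, 96.8 ± 69.6 in rdr1, exact permutation p = 0.7, n = 3) and at 9475 to 9496 (55.2 ± 20.9 in WT, 27.3 ± 17.8 in rdr1, exact permutation p = 0.2, n = 3) had groups that overlapped. Sense rRNA sequences did not move the same way: the 13252 tested had a median log2 fold change of 0.57, and 1 of them was called, TACCTGTCCAAAACAGAACGACC (chromosome 2, 5518 to 5540). It fell from 68.8 ± 20.1 to 2.80 ± 1.39 (limma adjusted p = 0.00986), and is named here after its value was seen.

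**Figure D2:**
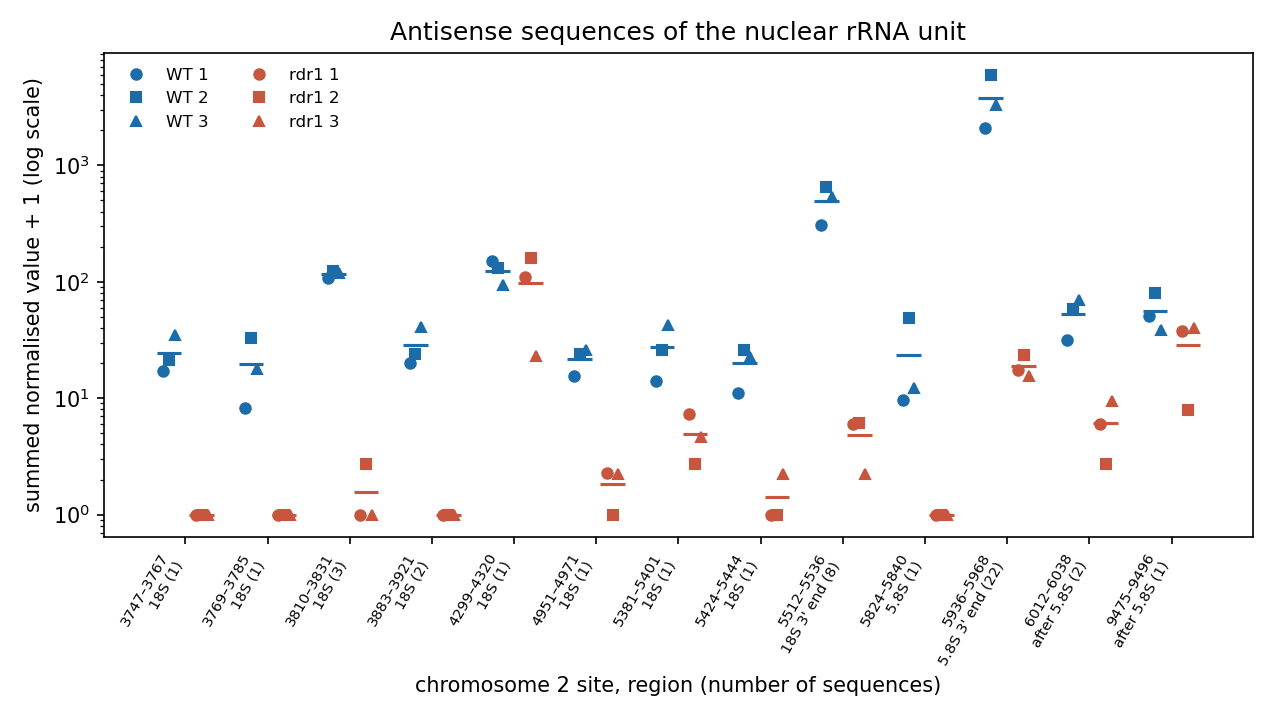
Summed normalised value plus 1 (vertical axis, log scale) of the antisense sequences at each of 13 sites of the nuclear rRNA unit (horizontal axis, positions on chromosome 2), with a point per library and a bar at the mean of the 3 libraries of each genotype. At the site from 5936 to 5968 the 3 WT libraries lay between 2098 and 5971 and the 3 rdr1 libraries between 14.5 and 22.3.

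The 5 sequences with the largest fall all lay in these antisense sites, each with 2 genomic matches. GGTGAGGGACGACGATT (chromosome 2, 5945 to 5961) had a value of 1573 ± 1304 in WT, or 5208 reads, and 0.418 ± 0.724 in rdr1, or 1 read, with a log2 fold change of -9.88 (SE 0.77) and a limma adjusted p of 2.58e-33. GGTGAGGGACGACGATTT (5944 to 5961) had 629 ± 368 in WT and 0 reads in rdr1, at least 462-fold lower against a floor of 3 reads over the 3 rdr1 libraries. GGATGGTGAGGGACGACGATT (5945 to 5965) had 342 ± 109 in WT and 0.418 ± 0.724 in rdr1. GATGGTGAGGGACGACGATT (5945 to 5964) had 252 ± 107 in WT and 0 reads in rdr1, at least 186-fold lower on the same floor. GTTTTGGACAGGTATCGACA (5512 to 5531) had 206 ± 84.7 in WT and 0 reads in rdr1, at least 152-fold lower on the same floor. Intervals and floors cover counting error only, because the reads carry no molecular identifiers that were used here.

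Outside rRNA and miRNA, 16 sequences were called, and they had the length of heterochromatic small interfering RNAs: 14 were of 24 nt and 2 of 23 nt, all with 1 genomic match, and 13 of them fell. The 3 sequences that rose were all of 24 nt and lay between genes. ATATAGTGTAGCTGGAAGACCTGT (chromosome 3, 7898458 to 7898481, 60 nt from AT3G22340) had 1.08 ± 0.948 in WT and 47.8 ± 11.7 in rdr1, with a log2 fold change of 4.66 (SE 1.12) and a limma adjusted p of 0.0208. ATGATTTCCAGTCATTTCGACGGT (chromosome 1, 10330095 to 10330118, 307 nt from AT1G29550) had 7.27 ± 12.6 and 54.0 ± 27.1, with 4.13 and 0.0392. AAATAAACAAGAACTTAGGTGATC (chromosome 5, 2656176 to 2656199, 306 nt from AT5G08250) had 33.3 ± 34.9 and 151 ± 48.3, with 2.97 and 0.0289. All 3 calls were lost with median of ratios scaling, a pseudocount of 20, and without WT replicate 3, rdr1 replicate 2 or rdr1 replicate 3. Those on chromosomes 1 and 3 were also lost without WT replicate 2, and those on chromosomes 1 and 5 with edgeR and DESeq2 on recovered reads. Over the libraries left out, the log2 fold change was 4.20 to 4.93 on chromosome 3 and 3.38 to 5.64 on chromosome 1. On chromosome 5 it was 1.74 (without WT replicate 3) to 3.94. With DESeq2 that on chromosome 1 was 1.95 (adjusted p = 0.865).

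MiR159b-5p, the strand opposite the usual mature arm of the MIR159B hairpin, fell in rdr1 to 18.6% of its WT level. GAGCTCCTTGAAGTTCAATGG (chromosome 1, 6220650 to 6220670, plus strand, within MIR159B, AT1G18075, 6220646 to 6220841) had 1 genomic match and a value of 1218 ± 316 in WT and 227 ± 64.9 in rdr1 (SD, n = 3 each), from 3860 and 514 reads. Its log2 fold change was -2.42 (SE 0.61) with a limma adjusted p of 0.0338 over all sequences, and 0.00522 adjusted over the list of annotated mature miRNAs alone. It was lower in 3 of 3 rdr1 libraries than in any WT library, with an exact permutation p of 0.1 (n = 3 each). The mature 3p sequences of miR159a, miR159b and miR159c, the arm that targets MYB transcription factor mRNAs, were not analysed here. The fall is therefore that of the opposite strand, and the level of the 3p arm cannot be read from it. Listed 3p variants of miR159b summed to 424 ± 225 in WT and 385 ± 54.2 in rdr1 (log2 fold change 0.05). Most of that sum came from a sequence shared with MIR159A and MIR159C. The series title names miR159b and is not independent of these libraries. The call was lost in 13 alternatives, edgeR (log2 fold change -2.42, adjusted p = 0.111) and median of ratios scaling (-2.89, adjusted p = 0.119) among them, and without WT replicate 2, WT replicate 3 or any rdr1 replicate (log2 fold changes from -2.64 to -2.24).

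Other sequences of the MIR159 hairpins did not pass the test. TTTGGATTGAAGGGAGCTC, a shortened 3p sequence shared by MIR159A, MIR159B and MIR159C, had 391 ± 200 in WT and 361 ± 45.5 in rdr1, a log2 fold change of 0.06. TTTGGATTGAAGGGAGCTCTTCA, a lengthened 3p sequence that matched MIR159B alone (chromosome 1, 6220813 to 6220835), had 33.6 ± 34.8 and 23.97 ± 9.18, a log2 fold change of 0.02 (SE 0.87). Summed over its sequences, the miR159 family had 2138 ± 774 in WT and 1152 ± 259 in rdr1, a log2 fold change of -0.84 (SE 0.49, limma adjusted p = 0.810). MiR159b-5p made up this difference: the other 10 sequences of the family summed to 921 ± 477 in WT and 926 ± 242 in rdr1 (exact permutation p = 1, n = 3 each). With miR159b-5p included, the family passed with DESeq2 (-1.16, adjusted p = 0.00112) and with quantile normalisation (-1.09, adjusted p = 0.0494). Of 60 families, limma called 0, edgeR called 0 and DESeq2 called 1. In limma 1 had an unadjusted p under 0.05, a smaller part than the 0.05 expected of unchanged families.

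The other mature miRNAs did not pass the test. Of 76 annotated mature sequences, 1 was called, miR159b-5p. Of the 36 listed sequences of the fixed list, limma called 0 over all sequences and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. With the deposited scaling 33 of the 36 were higher in rdr1, but 4 were higher with median of ratios scaling and 18 without WT replicate 1, so no direction is given for them. Copper-responsive miRNAs, which lower copper protein mRNAs when copper is short, had 2 of 5 members measured: miR408 had 194 ± 125 in WT and 303 ± 104 in rdr1, and miR398b had 11063 ± 5725 and 14019 ± 4896. Age pathway miRNAs, which act on juvenile and adult leaf traits, had 5 of 5 measured, among them miR156a with 5252 ± 3023 and 7225 ± 2215, miR157a with 25144 ± 13334 and 31037 ± 5666, miR172a with 29914 ± 15679 and 26719 ± 4591, miR172c with 729 ± 648 and 822 ± 279, and miR172e with 155 ± 74.8 and 122 ± 22.3. Leaf polarity miRNAs, which act on HD-ZIP III mRNAs, had 6805 ± 2916 and 8579 ± 895 for miR165a and 26914 ± 12102 and 32185 ± 699 for miR166a.

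Among miRNAs that act on the small RNA pathway itself, miR162a, which targets DCL1, had 2525 ± 1016 in WT and 3185 ± 337 in rdr1, and miR403, which targets AGO2, had 5925 ± 2736 and 6488 ± 196. MiR399b of the phosphate starvation list had 422 ± 187 and 466 ± 53.2, and miR319c of the miR159 and miR319 superfamily had 588 ± 269 and 641 ± 73.4. The annotated miRNAs with the next smallest p after miR159b-5p were miR172b-5p/miR172e-5p (55.0 ± 37.4 and 109 ± 46.9), miR850 (16.5 ± 11.9 and 31.4 ± 5.77), miR408, miR780.2 (46.9 ± 59.0 and 62.8 ± 41.8), miR158a-5p (772 ± 427 and 1091 ± 296), miR408-5p (66.9 ± 36.4 and 98.2 ± 10.2), miR156d-3p (189.7 ± 131 and 264 ± 100.1), miR839-5p (62.8 ± 50.8 and 90.1 ± 39.6) and miR3932a/miR3932b-3p (55.4 ± 45.5 and 78.0 ± 38.6). Each of these had a limma adjusted p of 0.753. Of the 13 lists fixed beforehand, 8 had at least 2 measured members and could be tested, and camera, camera with an estimated correlation and fry called 0 of them, with lowest adjusted p-values of 0.850, 0.915 and 0.662. The lowest unadjusted camera p was 0.344. The miR159 family, trans-acting siRNA and pollen-enriched lists had 0 measured members.

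**Figure D3:**
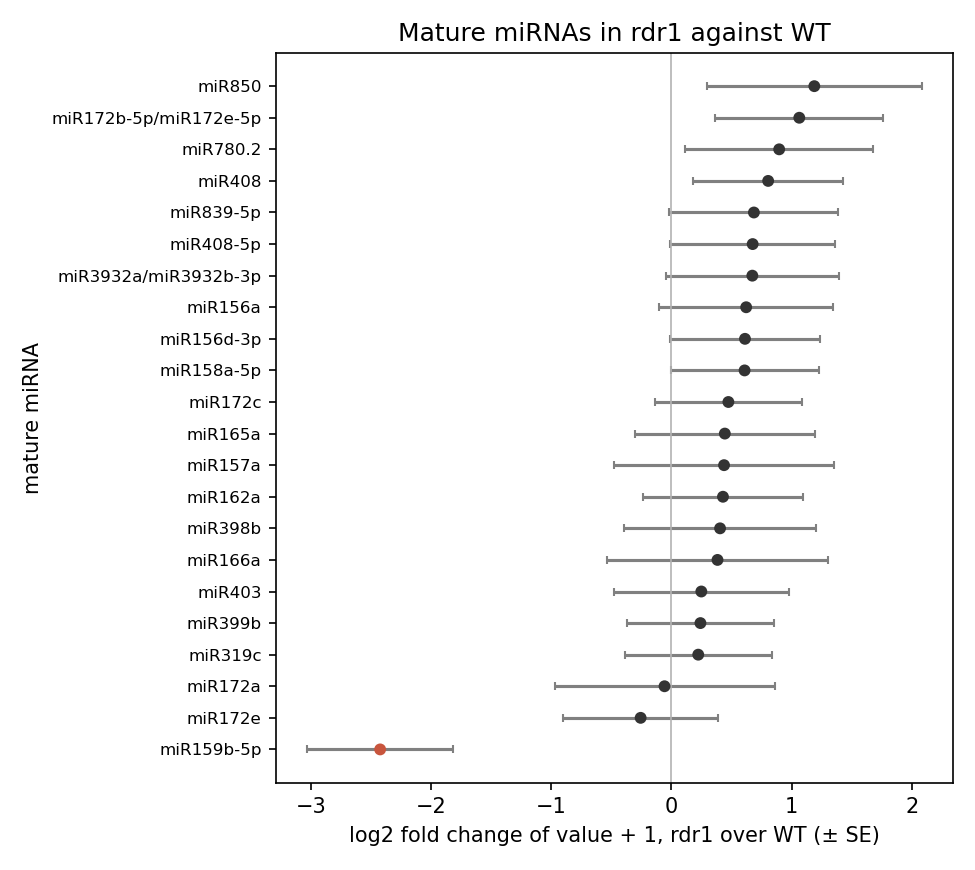
Log2 fold change of value plus 1 in rdr1 over WT (horizontal axis, bars ± SE, n = 3 each) of the 22 named mature miRNAs (vertical axis), with the miRNA that passed the limma test in red. MiR159b-5p lay at -2.42 and the other 21 between -0.26 and 1.19, and the sign of 8 of those 21 differed with median of ratios scaling.

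The listed small RNAs at 2 protein-coding genes fell to 0 reads in rdr1. These zeros cover listed sequences, which all matched the reference without mismatch and reached 20.07 in a library. They do not cover every small RNA of the genes. AT2G02440 (chromosome 2, 638012 to 639305, plus strand, uncharacterised protein) carried 2 sequences of 24 nt, both in an intron and on opposite strands, with 133 ± 32.2 in WT and 0 reads in rdr1, at least 97.8-fold lower. AT1G70080 (chromosome 1, 26394492 to 26397603, minus strand, a terpenoid cyclase superfamily protein) carried 5 antisense sequences of 24 nt over a coding exon and its boundary, with 138 ± 38.7 in WT and 0 reads in rdr1, at least 101-fold lower. Both had a limma adjusted p of 3.75e-06. Of 1217 loci tested, 4 were called by limma, 4 by edgeR and 6 by DESeq2. In limma 40 had an unadjusted p under 0.05, a smaller part than the 0.05 expected of unchanged loci. The other 2 called loci rested on 1 antisense sequence of 24 nt each, which ran past the annotated end of the gene. That at MIR774a (AT1G60073) had 14.8 ± 6.67 in WT and 0 reads in rdr1 (adjusted p = 0.0470 in limma). That at AT3G06705 rose from 6.73 ± 4.38 to 55.4 ± 14.2 (adjusted p = 0.0470 in limma). Both of these were lost with median of ratios scaling and without WT replicate 2, WT replicate 3, rdr1 replicate 2 or rdr1 replicate 3, and MIR774a also without WT replicate 1. Over the libraries left out the log2 fold change was -4.28 to -3.61 for MIR774a and 2.63 to 3.42 for AT3G06705.

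Among length and annotation classes, groups that did not overlap were found for tRNA alone, among 11 lengths from 18 to 28 nt and 9 classes. The 21-nt share was 21.4% ± 8.74 in WT and 26.3% ± 2.61 in rdr1 (exact permutation p = 0.5, n = 3 each), the 22-nt share 5.19% ± 0.924 and 5.30% ± 0.466 (exact p = 0.9), and the 24-nt share 5.40% ± 1.63 and 4.69% ± 1.22 (exact p = 0.6). Sequences of miRNA loci made up 24.1% ± 10.4 in WT and 28.7% ± 3.31 in rdr1 (exact p = 0.6), those of trans-acting siRNA loci 1.48% ± 0.586 and 1.80% ± 0.349 (exact p = 0.5), and rRNA 45.6% ± 7.84 and 47.5% ± 7.54 (exact p = 0.8). The tRNA share was 12.5% ± 0.985 in WT and 9.02% ± 0.950 in rdr1, with groups that did not overlap and an exact permutation p of 0.1 (n = 3 each), which is the smallest possible and was 0.75 after Benjamini-Hochberg adjustment over the 9 classes. As a share of distinct sequences the difference was -0.0557 percentage points, against -3.52 for the summed value. Of the 18124 sequences, 16055 were above 0 in all 6 libraries. The share of distinct sequences can thus barely differ between libraries, and does not bear on the difference in summed value. Small nuclear and nucleolar RNA made up 2.85% ± 1.27 and 1.46% ± 0.492 (exact p = 0.2), chloroplast sequences 7.86% ± 2.31 and 6.24% ± 3.38 (exact p = 0.5), mitochondrial sequences 0.105% ± 0.0419 and 0.0772% ± 0.0217 (exact p = 0.4), and protein-coding genes 1.46% ± 0.415 and 1.21% ± 0.601 (exact p = 0.5). Other nuclear sequences differed by 0.0251 percentage points (exact p = 1).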

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

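The tests with scaling to the miRNA sum, edgeR with TMM factors, removal of WT replicate 1 and rdr1 replicate 1 together, and sums or rRNA shares by strand were chosen after the result was seen; the others were set beforehand. The cause of each change below was not tested unless a cause is given. The 5 named falls kept their direction and their call under every alternative, while the 3 named rises kept their direction and lost the call in 33 fits in all. The loci AT2G02440 and AT1G70080 kept theirs under every alternative, and MIR774a and AT3G06705 lost theirs in 25 fits in all. The count of called sequences (39) was 24 with a pseudocount of 20, 15 with a mean of at least 20, 92 with quantile normalisation, 1225 with array weights (439 higher; the weights stopped before convergence), 67 with edgeR, 142 with DESeq2, 78 with edgeR and TMM factors, and 98 without WT replicate 1 and rdr1 replicate 1 together; leaving out a library in turn gave 11 to 72. Of the antisense rRNA sequences (21 called), 10 were called with a mean of at least 20, 35 with quantile normalisation, 44 with array weights, 41 with DESeq2 and 34 without WT replicate 1 and rdr1 replicate 1 together, with 7 to 26 over the libraries left out in turn. They were 58.3% of the falls in the main test, 75% with a pseudocount of 20, 71.4% with a mean of at least 20, 41.9% to 81.8% over the libraries left out, 42.2% with quantile normalisation, 40.3% with edgeR and TMM factors, 44.2% without WT replicate 1 and rdr1 replicate 1 together, and 5.60% with array weights.

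MiR159b-5p kept its direction under every alternative. Its call was lost with pseudocounts of 5 (-2.40, adjusted p = 0.0664) and 20 (-2.33, 0.204), a mean of at least 20 (-2.42, 0.0909), median of ratios scaling (-2.89, 0.119), quantile normalisation (-2.33, 0.0873), edgeR (-2.42, 0.111) and edgeR with TMM factors (-2.61, 0.147); these adjusted p-values are from limma unless edgeR is named. Leaving out a library gave -2.64 to -2.24. The number of annotated mature miRNAs called (1) was 0 with pseudocounts of 5 and 20, a mean of at least 20, median of ratios scaling, quantile normalisation, edgeR and edgeR with TMM factors, 4 with array weights, and 0 to 1 over the libraries left out; in the fixed list it was 1 (miR402, higher) with array weights and 0 otherwise, with 0 to 0 over the libraries left out. The miR159 family was the 1 family called with quantile normalisation, DESeq2, the miRNA sum and without WT replicate 1 and rdr1 replicate 1 together; 0 to 0 were called over the libraries left out. Of the 21 other named miRNAs, the sign differed for 12 with DESeq2, 8 with median of ratios scaling, 8 without WT replicate 1 and rdr1 replicate 1 together, 5 with TMM factors, 4 without WT replicate 1, and at most 3 elsewhere. Of the lists, 0 were called by camera with an estimated correlation, fry, the replicate block and median of ratios scaling, and 0 to 0 over the libraries left out; the other alternatives were not run for lists.

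The count of loci (4) was 20 with no filter on low values (where more loci were tested), 9 with strands summed separately, 8 with array weights, and 2 with a mean of at least 20, median of ratios scaling, a common total, quantile normalisation, the miRNA sum and edgeR with TMM factors, with 2 to 6 over the libraries left out. Differences of shares, rdr1 minus WT in percentage points, moved by over 1 SD with sequences of 1 genomic match to 1.496 for trans-acting siRNA, -5.37 for small nuclear and nucleolar RNA, 0.0284 for the mitochondrion, -0.902 for protein-coding genes and -0.449 for other nuclear sequences. As a share of distinct sequences they moved by over 1 SD to -0.0557 for tRNA and -0.0275 for small nuclear and nucleolar RNA. That share can barely differ between libraries, because most listed sequences were above 0 in all 6. Over the libraries left out the ranges were 1.05 to 9.64 for 21 nt, -0.408 to 0.478 for 22 nt, -1.34 to 0.219 for 24 nt, -0.155 to 10.13 for miRNA, 0.0984 to 0.653 for trans-acting siRNA, -4.02 to -2.97 for tRNA, -2.67 to 5.26 for rRNA, -1.91 to -0.678 for small nuclear and nucleolar RNA, -3.36 to 0.0145 for the chloroplast, -0.0498 to -0.00809 for the mitochondrion, -0.602 to -0.0178 for protein-coding genes and -0.231 to 0.333 for other nuclear sequences.

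With the replicate number as a block, 7 sequences, 6 antisense rRNA sequences (85.7% of the falls), 0 annotated mature miRNAs and 2 loci were called, and miR159b-5p had -2.42 with an adjusted p of 0.889 in limma. Whether the replicate numbers pair the libraries is not known. The deviations of same-numbered libraries from their group means correlated at -0.71, -0.30 and -0.53, which shows no shared effect. The differences in fragment length between libraries could hide such an effect, so pairing is not excluded and the blocked fit is not set aside. Depth limits what is seen in the shallowest library, rdr1 replicate 2, where 1 read is worth 1.71.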

Other observations

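All tests of explanations and of other splits in this part were chosen after the result was seen. Summed by strand, 9 gene strands passed the limma test, 8 lower and 1 higher in rdr1. The 8 are not separate results. The sums antisense to AT2G01020 and AT3G41979, in the rRNA units of chromosomes 2 and 3, came from the same sequences divided between both. Their values were identical (27.4 ± 19.2 in WT, 0 in rdr1). Both strands of AT2G02440 are also among the 8. The sum with the smallest p was antisense to AT3G06355, a long non-coding RNA gene inside the rRNA unit of chromosome 3 (14199575 to 14200076), with 1929 ± 1008 in WT and 11.4 ± 0.675 in rdr1 (log2 fold change -7.15), and its sequences also match the antisense sites of chromosome 2. A single antisense sequence at AT3G49230 (chromosome 3, 18254232 to 18255485) had 12.9 ± 7.70 in WT and 0 reads in rdr1. Trans-acting siRNA loci, whose precursors are copied by RDR6, summed per library to 12804, 18531 and 28012 in WT replicates 1 to 3 and 21220, 29026 and 21906 in rdr1 replicates 1 to 3 at TAS1C, and to 4725, 7524 and 11564 against 7628, 10243 and 8263 at TAS2.

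Summed over their 13 sites, antisense rRNA sequences were 30.6 times lower in rdr1, a ratio that differed between sites. Of their WT sum, 34.2% was of 17 nt, 13.9% of 18 nt, 3.19% of 19 nt and 10.7% of 20 nt. A further 16.6% was of 21 nt, 10.9% of 22 nt and 3.86% of 24 nt. More breakdown of rRNA in WT would lower sense sequences at the same sites, but the 1396 of these had a median log2 fold change of 0.45 (quartiles -0.54 and 0.87), against -4.62 for the antisense sequences. Fewer reads would not account for it, since 11128 reads were expected in rdr1 at the WT level and 334 were found. Double-stranded rRNA cut in WT and missing in rdr1 may account for it and stays open. As partners, 7 sense sequences of 20 to 24 nt were taken whose 5′ end lay 2 nt inside an antisense 3′ end. Their median log2 fold change was 0.69 below that of other sense sequences of that length (a difference of -0.69). The other end of such a pair was not checked. Sequences of 17 to 19 nt were left out on both strands, so this does not bear on that part of the antisense sum. Among the 7 is TACCTGTCCAAAACAGAACGACC (-4.24), the 1 called of 13252 sense sequences. All 7 lay below the median of the other sense sequences of 20 to 24 nt (0.59). Some of the 7 share a start, at 3749 or at 3812, so they are not independent of each other. The highest, at 0.50, lay at the site from 4299 to 4320, where the antisense groups overlapped. None lay at the largest antisense site (5936 to 5968), and breakdown fragments of the abundant sense strand can hide a fall. The partners as a set therefore do not decide.

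Sequences of 23 and 24 nt with 1 genomic match were merged within 300 nt into 338 clusters. Of these, 17 were seen in all 3 WT libraries alone and 5 in all 3 rdr1 libraries alone. The other 9 splits of the libraries gave at most 1. Of the 17, 9 held more than 1 sequence and the rest were single sequences. Of the 5, those on chromosomes 4 and 5 held 2 sequences each and the others 1. The 17 include the sequences already given at AT2G02440, AT1G70080, MIR774a and AT3G49230. As with the loci, absence covers listed sequences only, not every small RNA of a place. The clusters with the highest value were at chromosome 5, 21821203 to 21821265 (214 ± 27.6 in WT, 8 sequences, at least 157-fold lower in rdr1), and, in rdr1 alone, at chromosome 4, 8447004 to 8447029 (48.8 ± 22.6). Loss of RDR1 products as the whole of it would not account for the 5 clusters seen in rdr1 alone, nor would a single segment around RDR1 on chromosome 1 account for the 16 of 22 clusters on other chromosomes. Too few reads, as far as counting error goes, would not account for the 22 clusters as a set. The median number expected in the other genotype was 73.6 (lowest 25.3), above the 11.6 that the filter of the table itself ensures. The 22 were chosen for the 0 reads found there. With that filter an expectation near 0 could not arise, so this outcome was fixed by how sequences were listed and chosen. Differences in siRNA loci that the lines carried independently of RDR1 could also give clusters on both sides, and were not tested.

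The fall of miR159b-5p was weighed against 3 explanations. A homozygous sequence variant in rdr1 within the 21 nt of this sequence would leave no perfectly matching reads, and 514 were found. A variant elsewhere in or near MIR159B would leave such reads, and was not tested. Scaling would move other miRNAs alike, and the median log2 fold change of the other 75 annotated miRNAs was 0.39, against -2.42 (SE 0.61). Less MIR159B precursor may lower it and cannot be told apart from a change of this arm alone: the 3p sequence found only at MIR159B had 0.0155 (SE 0.87), from 172 reads, too few to decide.

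With 3 against 3 libraries the 10 splits are too few for a share under 0.05. As many calls as the real split were given, the real split included, by 2 of 10 splits for sequences (39 real, 138 highest other), 2 for annotated mature miRNAs (1 real, 1 highest other), 10 for the fixed list (0 real, 0 highest other), 10 for families (0 real, 1 highest other), 2 for loci (4 real, 142 highest other) and 2 for loci by strand (9 real, 135 highest other). The split with 138, 142 and 135 calls set WT replicates 1 and 2 and rdr1 replicate 3 against the rest, which follows the share of 28- to 34-nt sequences (35.3%, 26.2% and 17.7% against 9.94%, 4.87% and 15.7%) and points to a structure of the samples other than genotype.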
